A study of Homo sapiens with 4 samples.

How the data were processed

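RNA was measured in 4 libraries of normal human epidermal keratinocytes treated for 24 h with saline, LL-37, poly(I:C) or both. The passage was given as 6 in the treatment protocol and as 5 after plating in the growth protocol, per the labels' protocols, and which holds was not settled. All libraries came from 1 source of cells, so the groups had 1 library each. RNA was taken with the Purelink kit and libraries were made with the TruSeq HT kit, per the labels' protocols. Reads were aligned to hg19 with TopHat2 2.0.8 and quantified with Partek, per the submitters' processing notes. The deposited values were estimated counts (expected counts) per RefSeq transcript, with no scaling between libraries recorded by the authors, and 58.9% of the values had a fractional part of any size, with no tolerance for rounding. Strand handling was not given in the sources used here, so that reads of overlapping genes on opposite strands could not be separated, and reads of near-identical gene copies were shared in a way that was not stated.

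The 53678 transcript entries were summed to 26313 gene symbols, of which 10628 had several transcripts and 25180 (95.7%) were found in the reference gene tables. XIST and Y-linked genes, 108 symbols in all, were left out. Totals were 33805651, 33659528, 34708576 and 34011173 for control, LL-37, poly(I:C) and co-treatment. TMM factors from edgeR 4.0.16 were 1.05, 1.08, 0.926 and 0.946. A gene was tested when it reached 1 CPM in at least 1 library, which left 13460 genes.

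For each of 5 pairs of libraries the log2 ratio of TMM-normalised CPM was taken with a prior count of 0.5. Its 95% interval was the exact conditional binomial interval for 2 counts, rounded to whole numbers for that purpose. A call needed at least a 2-fold ratio and an interval excluding 1. No p-value was given for a pair, since a test on the reads of 2 libraries compares those libraries and not the conditions. The departure from the product of the single-treatment ratios was the log2 level of the co-treated library minus those of the 2 single-treatment libraries plus that of the control, with an interval from the sum of the reciprocals of the counts. Folds against a library with 0 reads were bounds against a floor of 3 counts per library.

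The additive model with terms for both agents was fitted with edgeR quasi-likelihood and 1 residual degree of freedom on 13458 genes, with Benjamini-Hochberg adjustment at 0.05. Its common biological coefficient of variation was 0.186. This value includes any true departure from additivity.

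Gene lists, 30 in all, were written before the data were examined, as were the comparisons, the calling rule and the alternatives. They covered 5 growth factor families, growth factor receptors, ERK pathway genes, LL-37 receptors, interferon and interferon-stimulated genes, double-stranded RNA sensing, MHC class I presentation, inflammatory, NF-κB and antimicrobial genes, basal, differentiation and wound-activated keratinocyte genes, cell cycle, p53, cell death, stress response, cholesterol synthesis and NRF2 genes. The remaining lists were markers of fibroblasts, melanocytes, endothelial cells and leukocytes, ribosomal protein genes and reference genes. Each list's median was placed among 10000 random lists matched on mean log2 CPM in 20 bins. Genes named in the report came from 3 sets: the 10 farthest each way by the interval bound nearest 1 among genes with 5 CPM in at least 1 library, up to 4 per list without that limit, and growth factor, sensor and keratin genes named in advance, also without it. Markers of other cell types are given with their levels whether or not they reached the filter. Results of some single genes are not reported here.

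The steps were tested on simulated data. For LL-37 against control, simulated 4-fold differences were called in 100% of cases with counting error alone or an assumed biological coefficient of variation up to 0.2, and in 80.0% at 0.4. Simulated 2-fold differences were called in 54.0%, 62.0%, 48.0% and 42.0% of cases at 0, 0.1, 0.2 and 0.4. Of 13260 simulated unchanged genes, 10, 18, 280 and 3136 were called at those settings, and the 95% interval held the simulated ratio for 95.3%, 50.1%, 32.9% and 19.2% of genes. The additive model, tested for its poly(I:C) term on 13458 genes at 0.2, called 100% of 4-fold and of 8-fold differences and 4 unchanged genes. That simulation held no effect of LL-37 and no departure from additivity. Its recovery therefore does not carry over to genes that depart from additivity.

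Alternatives were DESeq2 size factors, total counts only, upper-quartile factors, no filter, a filter of 5 CPM, a prior count of 5, a 4-fold rule, a 99.9% interval, leaving out the 10 most abundant genes, random lists without matching, the mean of list members, the sum of single-treatment excesses as reference, the Spearman correlation, a DESeq2 1.42.0 Wald test, the legacy edgeR quasi-likelihood, and a model with the tested agent only. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.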

Results

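Gene expression was measured by RNA sequencing in normal human epidermal keratinocytes, the primary cells that form the outer layer of the skin. The cells were treated for 24 h with phosphate-buffered saline as the control, with 1.75 µM LL-37, with 0.1 µg/ml poly(I:C), or with both agents at those doses. The label of the poly(I:C) library gives high molecular weight poly(I:C), while that of the co-treated library does not state the weight. LL-37 is the antimicrobial peptide released from the cathelicidin precursor encoded by CAMP, and poly(I:C) is a synthetic double-stranded RNA that mimics viral or damage-associated RNA. The study asked how growth factor genes respond to the peptide, to the double-stranded RNA and to their combination. Each of the 4 conditions had 1 library, and all of them came from a single source of cells, so that differences between conditions had no replicate check. The libraries held 33805651 (control), 33659528 (LL-37), 34708576 (poly(I:C)) and 34011173 (LL-37 and poly(I:C)) estimated read counts over genes. Between 17602 and 17737 genes had at least 1 read in a library, and 13460 genes reached 1 CPM (counts scaled to the library total) in at least 1 of the 4. A gene was called higher or lower when the ratio of 2 libraries was at least 2-fold and its 95% counting interval excluded 1. Values below are log2 ratios of normalised CPM, and ranges in parentheses are those intervals, which cover counting error only and say nothing of the spread between cultures.

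The comparison of the LL-37 library with the control library shows what went with the peptide alone. Genes of the cell division machinery were far lower: TOP2A, which untangles DNA before mitosis, was 27.9-fold lower (−4.80, −4.95 to −4.66) and CDK1, the kinase that drives entry into mitosis, was 17.4-fold lower (−4.12, −4.29 to −3.96). Genes at the other end were the IL-33 receptor gene IL1RL1 at 8.75 (8.06 to 9.68), the decoy receptor gene IL13RA2 at 6.49 (5.79 to 7.41), the stromelysin gene MMP3 at 5.69 (5.42 to 6.00) and the cytokine gene IL24 at 5.45 (5.23 to 5.70). FGF2, a growth factor for fibroblasts and endothelial cells, was 32.7-fold higher (5.03, 4.90 to 5.17). In all, 1827 genes were higher and 1859 lower than in the control, together 27.4% of those tested.

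Of the 28 cell cycle genes, 27 were lower in the LL-37 library, 0 were higher and 1 was neither. Their median was −3.48, against −0.32 to 0.35 for the middle 95% of random lists matched on expression. The ribonucleotide reductase gene RRM2 was at −4.65 (−4.79 to −4.51) and the mitotic kinase gene AURKB at −4.29 (−4.63 to −3.98). Among the 20 cholesterol synthesis genes, 15 were lower, 0 were higher and 5 were neither, with a median of −1.25. HMGCS1, which makes the precursor of mevalonate, was at −2.65 (−2.69 to −2.61). Stress genes went the other way. The unfolded protein and integrated stress response list had 11 of 21 members higher and 2 lower (median 1.00), with ATF3 at 5.18 (4.99 to 5.38), PPP1R15A at 3.89 (3.81 to 3.97) and DDIT3 at 3.06 (2.94 to 3.19), while the endoplasmic reticulum gene CRELD2 was at −3.54 (−3.72 to −3.37). Among 16 targets of NRF2, the regulator of the oxidative stress response, 9 were higher and 2 lower (median 1.26), including OSGIN1 at 3.39 (3.16 to 3.64) and AKR1C1 at 2.99 (2.91 to 3.08). Among 20 p53 target genes 11 were higher and 0 lower (median 1.07), including PHLDA3 at 2.27 (2.21 to 2.35) and GADD45A at 1.97 (1.91 to 2.03).

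Interferon-stimulated genes were lower with LL-37 alone in 21 of 46 cases, higher in 5 and neither in 20, with a median of −0.89 against −0.22 to 0.26 for matched random lists. The antiviral genes IFIT1 at −3.70 (−4.23 to −3.24) and OAS2 at −3.26 were among the lower members. Cytokine and chemokine genes were divided: 16 of 35 were higher, 8 lower and 11 neither, with the neutrophil chemokine gene CXCL2 at 5.51 (5.16 to 5.91) and IL6 at 5.62 (5.01 to 6.40), while CXCL14, a chemokine gene of resting epithelium, was at −5.31 (−6.34 to −4.56). Of 20 NF-κB target and feedback genes, 13 were higher and 0 lower (median 1.08), among them PTGS2, which encodes cyclooxygenase-2, at 3.35 (3.29 to 3.42). Of 11 antimicrobial protein genes, 8 were higher and 0 lower (median 2.84), among them LCN2 at 5.34 (4.95 to 5.80) and RNASE7 at 3.74 (3.59 to 3.91). The defensin genes DEFB103A and DEFB103B carried identical values of 5.28 (4.06 to 7.34), and reads of such near-identical copies cannot be assigned to one of them. Both are members of the antimicrobial list, so the same measurement enters its counts and medians more than once in every comparison.

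Keratinocyte differentiation genes were mostly higher with LL-37: 15 of 23 were higher, 3 lower and 5 neither, with a median of 1.71. CRCT1, a gene of the cornified layer, was at 4.93 (4.33 to 5.69) and SPRR2A, a cornified envelope precursor gene with close paralogs, at 4.29 (4.07 to 4.54). Among 18 basal keratinocyte genes, 1 was higher (LAMB3, 2.37, 2.36 to 2.39), 5 were lower and 12 were neither, and the basal keratin genes KRT5 and KRT14 were at −2.19 (−2.19 to −2.18) and −1.66 (−1.67 to −1.65). The wound-activated list split into 6 higher, 4 lower and 8 neither, with MMP1 at 4.18 (4.15 to 4.21) and SERPINB2 at 4.14 (4.10 to 4.17); its median of −0.11 and its mean of 0.72 differed in sign. The double-stranded RNA sensing list had 5 of 22 members higher and 2 lower (median 0.05), with TLR3 at −1.62 (−2.08 to −1.20). Among 18 genes of antigen presentation by MHC class I, 2 were higher and 3 lower, and the median of −0.04 became 0.00 when libraries were scaled by total count only. Cell death genes had 4 higher and 4 lower of 17, with a median of 0.06 and a mean of −0.13, and TNFSF10, which encodes the death ligand TRAIL, was at −2.88 (−3.68 to −2.21).

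The comparison of the poly(I:C) library with the control library shows what went with double-stranded RNA alone. It was led by genes of the antiviral response. The chemokine gene CXCL10 was 1543-fold higher (10.59, 10.06 to 11.25), the antiviral genes RSAD2 and MX2 were at 10.09 (9.54 to 10.76) and 10.21 (9.33 to 11.52), and the gelatinase gene MMP9 was at 9.42 (8.99 to 9.92). C15orf48 had 1 read in the control and 2745 in the poly(I:C) library, a log2 ratio of 10.96 with an interval of 9.09 to 16.87. Genes that were lower included CXCL14 at −5.03, the carboxypeptidase gene CPA4 at −3.73 (−3.89 to −3.57), the long non-coding RNA H19 at −3.13 (−3.45 to −2.83) and the imprinted gene MEST at −2.83 (−2.96 to −2.71).

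All 46 interferon-stimulated genes were higher with poly(I:C), with a median of 4.84, including OASL at 9.08 (8.60 to 9.67) and CMPK2 at 9.03 (8.37 to 9.88). Interferon genes themselves were near absent from the control. IFNL1 had 0 reads in the control and 134 with poly(I:C), at least 49.4-fold higher when the control was set to 3 counts, and IFNB1 had 0 and 33 reads, at least 12.2-fold higher. IFNL2 and IFNL3 share most of their sequence and had 19 and 8 reads with poly(I:C) against 0 in the control, and the keratinocyte interferon gene IFNK was at 1.58 (1.22 to 1.97). In total 5 of 6 interferon genes were higher, with a median of 4.75 that was 2.21 when control genes without reads were set to the floor of 3 counts. Sensors of double-stranded RNA were higher as well: 14 of 22 genes of that list were higher and 0 lower (median 1.49), with DDX58, which encodes RIG-I, at 5.85 (5.74 to 5.97), IFIH1, which encodes MDA5, at 5.31 (5.14 to 5.48) and TLR3 at 2.48 (2.25 to 2.72). All 18 genes of antigen presentation by MHC class I were higher (median 2.33), with the proteasome subunit gene PSMB9 at 3.87 (3.64 to 4.12) and the regulator gene NLRC5 at 3.55 (3.33 to 3.78).

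Inflammatory genes were higher with poly(I:C) in 30 of 35 cases and lower in 1, with a median of 3.57, or 3.39 with genes lacking control reads at the floor. They included CCL5 at 8.25 (7.40 to 9.46) and the epithelial interleukin gene IL36G at 8.07 (7.13 to 9.49). NF-κB genes were higher in 17 of 20 cases and lower in 0 (median 2.05), among them the adhesion molecule gene ICAM1 at 6.47 (6.27 to 6.69) and the survival gene BIRC3 at 4.96 (4.80 to 5.13). All 11 antimicrobial protein genes were higher (median 3.06), with S100A8 at 3.98 (3.65 to 4.33) and S100A9 at 3.06 (2.90 to 3.23). Wound-activated genes were higher in 14 of 18 cases and lower in 1 (median 1.87), with MMP10 at 5.74 (5.47 to 6.03), the keratin gene KRT6B, which has a close paralog, at 4.88 (4.83 to 4.94) and the urokinase receptor gene PLAUR at 4.75 (4.59 to 4.93). Differentiation genes were higher in 18 of 23 cases and lower in 3 (median 2.03), with CRCT1 at 3.50 (2.87 to 4.28) and the transcription factor gene OVOL1 at 2.90 (2.58 to 3.24). Basal genes had 5 higher and 0 lower of 18 (median 0.47), among them the laminin gene LAMA3 at 2.20 (2.19 to 2.21), while KRT5 was at −0.56 and KRT14 at −0.70, neither being called. Cell death genes were higher in 10 of 17 cases and lower in 0 (median 1.07), with TNFSF10 at 5.13 (4.89 to 5.39).

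Other lists had fewer calls with poly(I:C) alone. Of the 28 cell cycle genes, 4 were lower, 0 were higher and 24 were neither, but their median of −0.65 lay below the matched random range of −0.20 to 0.21, with TOP2A at −1.14 (−1.19 to −1.09). Of 20 cholesterol synthesis genes 0 were called (median −0.173, just below the matched random range of −0.153 to 0.285). Of 16 NRF2 targets 1 was higher and 1 lower (median −0.38, below the matched random range of −0.22 to 0.31). Of 20 p53 targets 2 were higher and 2 lower (median 0.23), with PMAIP1, a pro-apoptotic gene, at 3.50 (3.43 to 3.57). Stress response genes had 5 higher and 0 lower of 21 (median 0.329, above the matched random range of −0.169 to 0.276), with ATF3 at 3.73 (3.53 to 3.94). Altogether 1207 genes were higher and 543 lower, so that 69.0% of the calls were higher. This split depended on scaling: with total counts only, which shifted the median of all genes by −0.184, 845 genes were lower and 54.0% of the calls were higher.

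The co-treated library was compared with the control to show what went with the combination. Interferon-stimulated genes were at their highest levels of the 4 libraries for RSAD2 at 11.95 (11.41 to 12.62), OASL at 10.61 (10.13 to 11.19) and IFIT2 at 10.24 (9.98 to 10.53), and all 46 were higher than in the control (median 5.42). KLHDC7B reached 12.39 (10.88 to 15.77) from 2 reads in the control. At the same time all 28 cell cycle genes were lower (median −4.60), with TOP2A 145.9-fold lower (−7.19, −7.57 to −6.85) and CDK1 62.6-fold lower (−5.97, −6.32 to −5.65). IFNL1 was at least 349-fold, IFNB1 at least 119-fold, IFNL2 at least 104-fold and IFNL3 at least 64.4-fold higher than a control floor of 3 counts, and 5 of 6 interferon genes were higher (median 8.88, or 6.35 with the floor). The counts were 2426 genes higher and 2294 lower, 35.1% of those tested, and with total counts only, which shifted the median of all genes by −0.152, they were 2073 higher and 2766 lower.

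In the co-treated library cholesterol synthesis genes were lower in 15 of 20 cases (median −1.39), as with LL-37, and HMGCS1 was at −2.79 (−2.83 to −2.74). Stress response genes had 11 higher and 4 lower of 21 (median 1.16), with ATF3 at 6.58 (6.39 to 6.79). NRF2 targets had 7 higher and 2 lower of 16 (median 0.58), and p53 targets 8 higher and 3 lower of 20 (median 0.83), with PMAIP1 at 4.86 (4.79 to 4.92). NF-κB genes were higher in 17 of 20 cases (median 2.57), antimicrobial genes in all 11 (median 4.44, or 3.88 with the floor), MHC class I genes in 17 of 18 (median 2.57), sensing genes in 15 of 22 (median 1.82) and cell death genes in 12 of 17 (median 1.34). Inflammatory genes had 28 higher and 5 lower of 35 (median 2.99), with IL6 209.9-fold higher (7.71, 7.11 to 8.49). Differentiation genes had 14 higher and 3 lower of 23 (median 1.81), with OVOL1 at 4.03 (3.73 to 4.36) but CALML3, a calmodulin-like gene of epithelium, at −5.36 (−7.86 to −3.99). Wound-activated genes had 12 higher and 2 lower of 18 (median 1.74), with SERPINB2 at 5.66 (5.63 to 5.70). Basal genes had 5 higher and 5 lower of 18 (median −0.42), with LAMB3 at 2.97 (2.95 to 2.98), the anchoring fibril gene COL7A1 at −2.34 (−2.41 to −2.27) and KRT5 at −1.77 (−1.77 to −1.76).

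**Figure D1:**
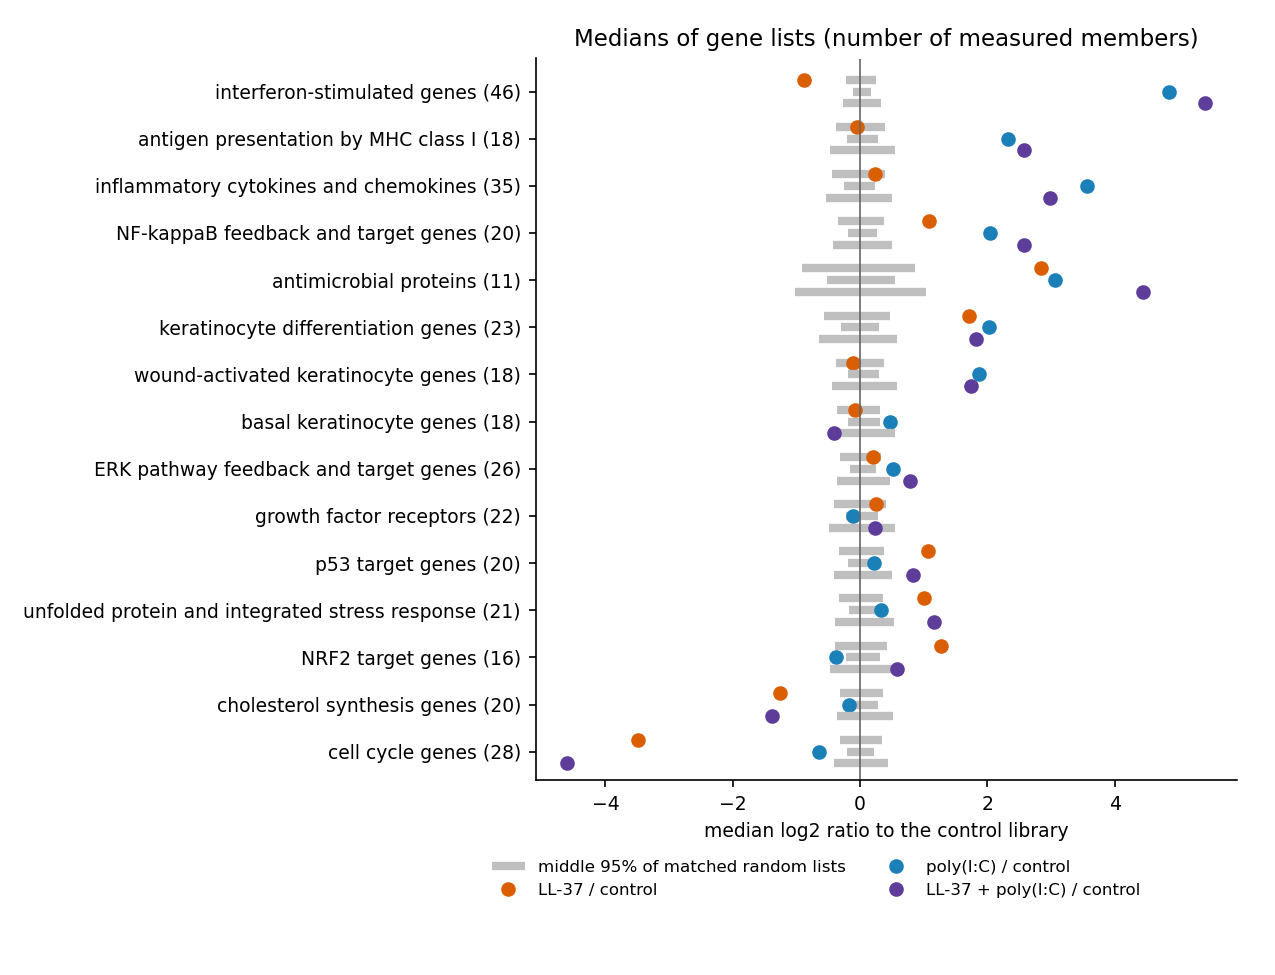
Median log2 ratio to the control library of 15 gene lists (points, coloured by treatment), with the number of measured members in parentheses and, as grey bars, the middle 95% of medians of random lists matched on expression. Interferon-stimulated genes lay at 4.84 with poly(I:C) and −0.89 with LL-37, and cell cycle genes at −3.48 with LL-37 and −4.60 with both agents.

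Growth factor genes, the subject of the study, went both ways in each treatment. Of 90 genes on the growth factor lists 50 were measured. In the LL-37 library 12 were higher, 12 lower and 26 neither. With poly(I:C) 17 were higher, 10 lower and 23 neither, and with both agents 15 were higher, 15 lower and 20 neither. Against control, family medians lay inside the matched random ranges with the following exceptions. EGF family ligands were at 0.872 with poly(I:C), above −0.376 to 0.575. Other growth and colony-stimulating factors were at −0.853 with both agents, below −0.67 to 0.74.

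In the EGF family, HBEGF, which encodes a heparin-binding ligand of the EGF receptor, was 7.14-fold higher with LL-37 (2.84, 2.73 to 2.94), at 2.89 with poly(I:C) and 10.2-fold higher with both (3.35, 3.25 to 3.45). TGFA was at 0.68, 1.24 (1.19 to 1.28) and 1.88 (1.84 to 1.93) in the same order, the first of these not being called. EREG was at 1.60 (1.55 to 1.65) with LL-37 but at 0.38 with poly(I:C) and 0.68 with both. AREG, the most abundant ligand gene of this family in the control at 1069 CPM, was at 0.58 with LL-37, −0.17 with poly(I:C) and −1.01 (−1.04 to −0.99) with both. EPGN was lower with each agent alone (−1.82, −1.94 to −1.71 with LL-37, and −1.61 with poly(I:C)) and at −0.10 with both. NRG1 was called with both agents only (−1.37, −1.47 to −1.27). BTC had 1, 2, 22 and 97 reads in the control, LL-37, poly(I:C) and co-treated libraries, with ratios of 4.03 (1.98 to 9.97) for poly(I:C) and 6.14 (4.23 to 12.06) for both. Across the 9 measured members the list had 2 higher and 2 lower with LL-37 (median 0.58), 4 higher and 2 lower with poly(I:C) (median 0.87), and 3 higher and 3 lower with both, where the median of −0.10 and the mean of 0.74 differed in sign.

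FGF2 was higher in each treated library, at 5.03 with LL-37, 3.07 (2.93 to 3.21) with poly(I:C) and 5.50 (5.37 to 5.64) with both. FGF19, which encodes an endocrine FGF, had 5 reads in the control, 356 with LL-37, 3 with poly(I:C) and 108 with both, with ratios of 5.97 (4.88 to 7.75) for LL-37 and 4.44 (3.31 to 6.23) for both. FGF1 was at −1.78 (−2.38 to −1.25) with LL-37. Of the 5 measured FGF genes 2 were higher and 1 lower with LL-37 (median −0.09, mean 1.76), 1 higher and 0 lower with poly(I:C) (median 0.00), and 2 higher and 1 lower with both (median 0.66).

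Among 8 genes of the VEGF, PDGF and angiopoietin family, LL-37 went with 1 higher and 3 lower (median −0.47), poly(I:C) with 3 higher and 1 lower (median 0.25), and both with 2 higher and 2 lower (median −0.32). VEGFA, the main angiogenic factor gene, was at 1.70 (1.66 to 1.75), 1.30 (1.25 to 1.34) and 1.55. VEGFC, a lymphatic growth factor gene, was at −0.62 with LL-37 and at 1.67 (1.61 to 1.72) and 1.43 (1.38 to 1.49) in the libraries with poly(I:C). ANGPTL4 was at −2.45 with LL-37 and 1.37 (1.16 to 1.59) with poly(I:C). PDGFC was at −1.37 with LL-37 and −2.20 (−2.37 to −2.03) with both.

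Of 11 genes on the TGF-β superfamily list, 4 were higher and 2 lower with LL-37 (median 0.04), 3 and 3 with poly(I:C) (median 0.02, and −0.17 with total counts only), and 3 and 2 with both (median 0.43). BMP1, which is on that list, encodes a protease and not a ligand. INHBA, which encodes the activin A subunit, was 10.5-fold higher with LL-37 (3.39, 3.27 to 3.51), 20.4-fold with poly(I:C) (4.35, 4.23 to 4.47) and 29.1-fold with both (4.87, 4.75 to 4.98). BMP2 was at 2.18 (1.98 to 2.38), 2.73 (2.54 to 2.92) and 2.86 (2.67 to 3.06). GDF15, a stress-induced cytokine gene, was 19.1-fold higher with LL-37 (4.26, 3.99 to 4.55), lower with poly(I:C) (−1.49, −2.09 to −0.95) and at 0.73 with both. TGFB2 was at −0.60 with LL-37, −2.34 (−2.70 to −2.02) with poly(I:C) and −2.79 (−3.19 to −2.42) with both.

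The 17 other growth and colony-stimulating factor genes had 3 higher and 4 lower with LL-37 (median 0.25), 6 higher and 4 lower with poly(I:C) (median 0.20), and 5 higher and 7 lower with both, where the median of −0.85 and the mean of 0.34 differed in sign. CSF2, which encodes the granulocyte-macrophage colony-stimulating factor, had 9 reads in the control and 220 with LL-37, and was at 6.62 (5.77 to 7.84) with poly(I:C) and 6.68 (5.83 to 7.89) with both. CSF3 was at 0.93 with LL-37 and at 3.66 (3.44 to 3.90) and 3.58 (3.36 to 3.82) in the libraries with poly(I:C), and midkine, encoded by MDK, was at 0.43, 2.58 (2.29 to 2.89) and 3.03 (2.75 to 3.33). CTGF, a matricellular protein gene, was lower in each treated library, at −2.59 (−2.67 to −2.51), −1.30 (−1.36 to −1.25) and −2.14 (−2.22 to −2.07). GAS6 was at −1.75 (−1.80 to −1.69) with LL-37 and 0.20 with poly(I:C). KITLG, the ligand gene of the melanocyte and mast cell receptor KIT, was at 0.60 with LL-37 and 4.23-fold lower with poly(I:C) (−2.08, −2.19 to −1.97).

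**Figure D2:**
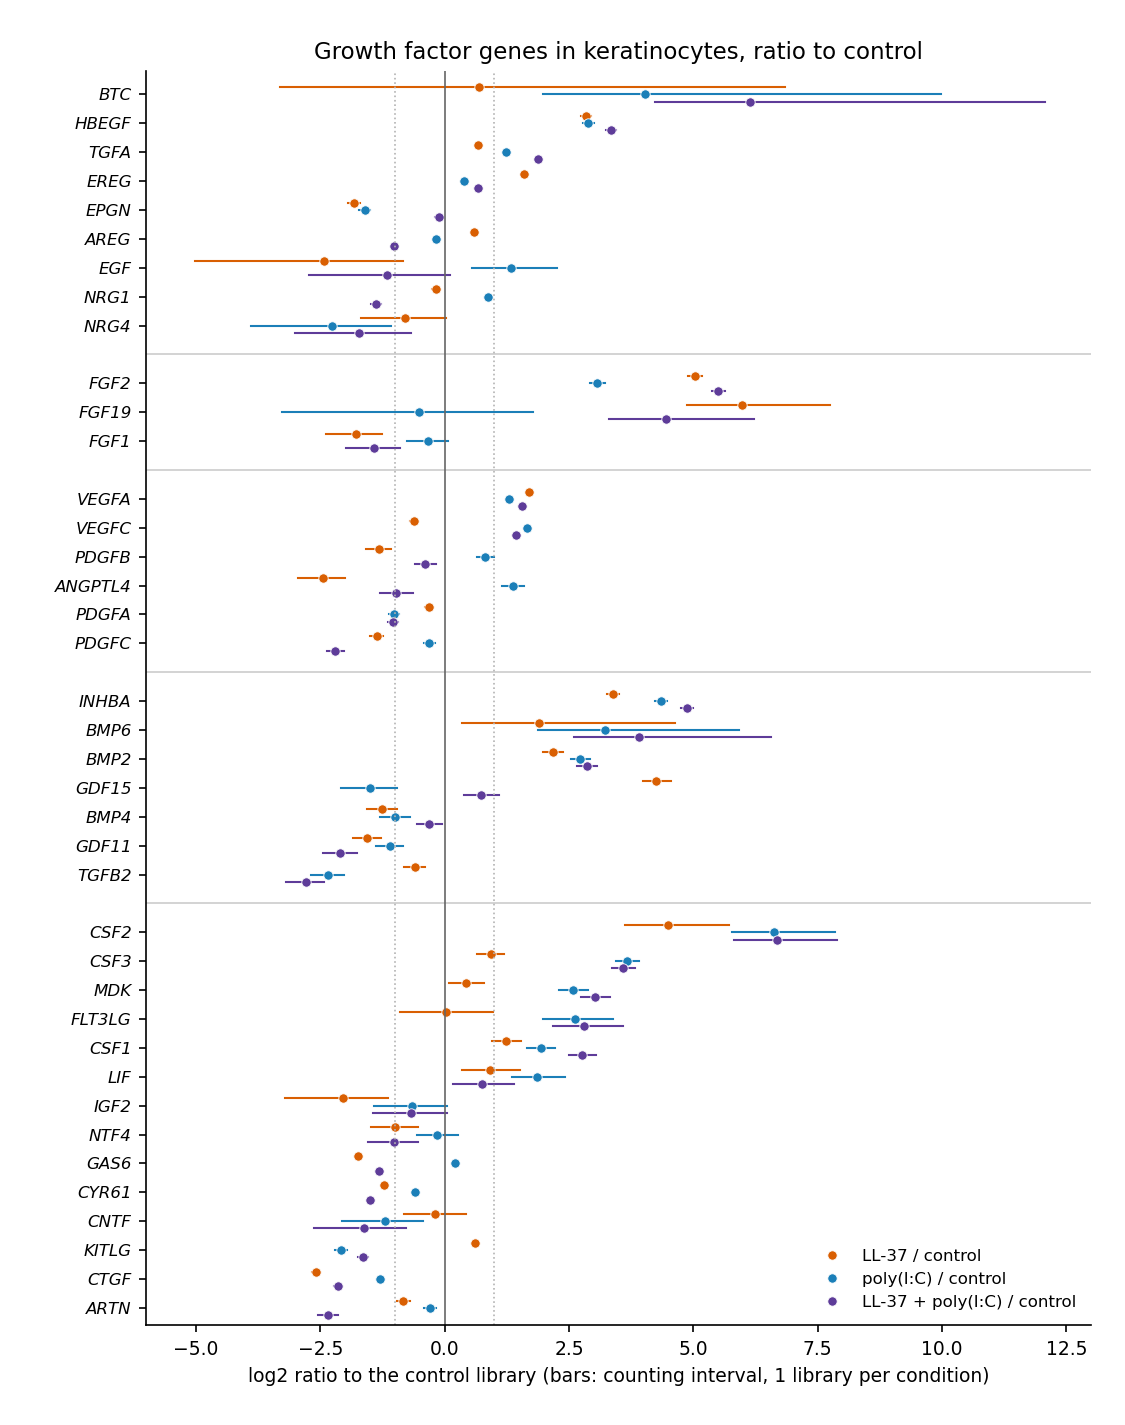
Log2 ratio to the control library of the growth factor genes reported here that were called in at least 1 treatment, with 95% counting intervals (bars), 1 library per condition; lines separate the 5 families and dotted lines mark 2-fold. INHBA lay at 3.39, 4.35 and 4.87 with LL-37, poly(I:C) and both, and GDF15 at 4.26, −1.49 and 0.73.

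Growth factor receptor genes, which encode the proteins that bind these ligands, were measured as well. Of 22 measured, 3 were higher and 4 lower with LL-37 (median 0.24, mean −0.06), 0 higher and 3 lower with poly(I:C) (median −0.11), and 2 higher and 7 lower with both (median 0.24, mean −0.36). FGFR3 was at −2.86 (−3.18 to −2.57) with LL-37 and −4.34 (−4.91 to −3.85) with both, and IGF2R at 1.81 (1.77 to 1.85) with LL-37. EGFR was at 1.00 (0.95 to 1.04) with LL-37, short of a call, and at 0.05 and 0.53 in the others. Of 26 ERK pathway feedback and target genes, which read out growth factor signalling, 9 were higher and 3 lower with LL-37 (median 0.21, inside the matched random range of −0.31 to 0.33), 6 and 2 with poly(I:C) (median 0.52, above −0.16 to 0.25), and 10 and 2 with both (median 0.78, above −0.37 to 0.47). PHLDA1 was at 2.27 (2.25 to 2.29) with LL-37 and KLF6 at 3.32 (3.28 to 3.36) with both. Of 7 measured genes for reported receptors and uptake of LL-37, 1 was higher and 2 lower with LL-37 (median −0.12), 1 higher and 0 lower with poly(I:C) (median 0.05, and −0.14 with total counts only), and 1 higher and 3 lower with both (median 0.43, mean −0.23). The scavenger receptor gene SCARA3 was at −2.83 (−3.03 to −2.64) with LL-37. CAMP itself did not reach the expression filter.

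The co-treated library was set against the poly(I:C) library to show what the peptide added in the presence of double-stranded RNA. MMP3 was at 6.14 (5.74 to 6.63), IL1RL1 at 5.54 (5.22 to 5.90), the shared value of DEFB103A and DEFB103B at 5.48 (4.82 to 6.45) and IL13RA2 at 4.94 (4.61 to 5.31). MMP9 was at −5.90 (−6.04 to −5.76) and TOP2A at −6.05 (−6.43 to −5.71). Type I and type III interferon genes were higher still, with IFNB1 at 3.27 (2.77 to 3.86), IFNL1 at 2.82 (2.56 to 3.09) and, with shared sequence, IFNL2 at 3.83 (3.22 to 4.64) and IFNL3 at 4.44 (3.44 to 5.68), so that 5 of 6 interferon genes were higher and 0 lower (median 3.05). Here 1084 genes were higher and 1551 lower, 19.6% of those tested.

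Interferon-stimulated genes were higher in the co-treated than in the poly(I:C) library in 9 of 46 cases and lower in 0, and their median of 0.59 lay above the matched random range of −0.19 to 0.19. IFIT2 was at 2.84 (2.82 to 2.87), RSAD2 at 1.86 (1.84 to 1.88) and OASL at 1.53. Cytokine and chemokine genes were divided into 9 higher, 7 lower and 19 neither (median −0.37), with IL6 at 3.01 (2.87 to 3.15) and the neutrophil chemokine genes CXCL6 at −3.76 (−4.35 to −3.27) and CXCL5 at −2.73 (−2.85 to −2.61). Cell cycle genes were lower in 27 of 28 cases (median −3.94) and cholesterol synthesis genes in 13 of 20 (median −1.45), with HMGCS1 at −2.85 (−2.90 to −2.81). NRF2 targets were higher in 6 of 16 cases (median 0.75), with AKR1C1 at 3.11 (3.01 to 3.22), p53 targets in 6 of 20 (median 0.79), with CDKN1A at 1.33 (1.30 to 1.36), and stress response genes in 4 of 21 with 4 lower (median 0.60). Basal genes were lower in 4 of 18 cases and higher in 0 (median −0.63), including TP63, the master regulator of the epidermal lineage, at −1.82 (−1.86 to −1.78). Among growth factor genes 6 were higher, 10 lower and 34 neither, with FGF19 at 4.96 (3.58 to 7.47), FGF2 at 2.44 (2.38 to 2.49), GDF15 at 2.22 (1.71 to 2.80), NRG1 at −2.24 (−2.34 to −2.15) and ANGPTL4 at −2.34 (−2.65 to −2.05).

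The co-treated library was set against the LL-37 library to show what double-stranded RNA added in the presence of the peptide. RSAD2 was at 12.56 (11.90 to 13.41), IFIT1 at 11.32 (10.88 to 11.84) and CXCL10 at 11.93 (10.86 to 13.70), and 45 of 46 interferon-stimulated genes were higher (median 6.16). GDF15 was at −3.53 (−3.76 to −3.31), the transcription factor gene FOXA2 at −3.14 (−3.42 to −2.88) and KITLG at −2.24 (−2.34 to −2.15). Inflammatory genes were higher in 21 of 35 cases and lower in 4 (median 1.98), and all 18 MHC class I genes were higher (median 2.71). Of growth factor genes 14 were higher, 10 lower and 26 neither, with MDK at 2.60 (2.35 to 2.85), VEGFC at 2.06 (1.99 to 2.12), CSF2 at 2.18 (1.97 to 2.40), AREG at −1.59 (−1.62 to −1.57) and TGFB2 at −2.19 (−2.60 to −1.80). Cell cycle genes were lower in 15 of 28 cases and higher in 0 (median −1.10). Of all genes 1021 were higher and 603 lower, 62.9% of the calls being higher, and with total counts only, which shifted the median of all genes by −0.197, 983 were lower and 45.7% of the calls were higher.

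The ratios for LL-37 without and with poly(I:C) share no library and could be compared across genes, which are not independent replicates. Their Pearson correlation over 13460 genes was 0.802, and 812 genes were higher in both against 147.1 if the lists were independent, while 1186 were lower in both against 214.2. Opposite calls were made for 36 genes. The ratios for poly(I:C) without and with LL-37 had a Pearson correlation of 0.752 and a Spearman correlation of 0.602, with 695 genes higher in both against 91.6, 191 lower in both against 24.3, and 33 opposite.

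**Figure D3:**
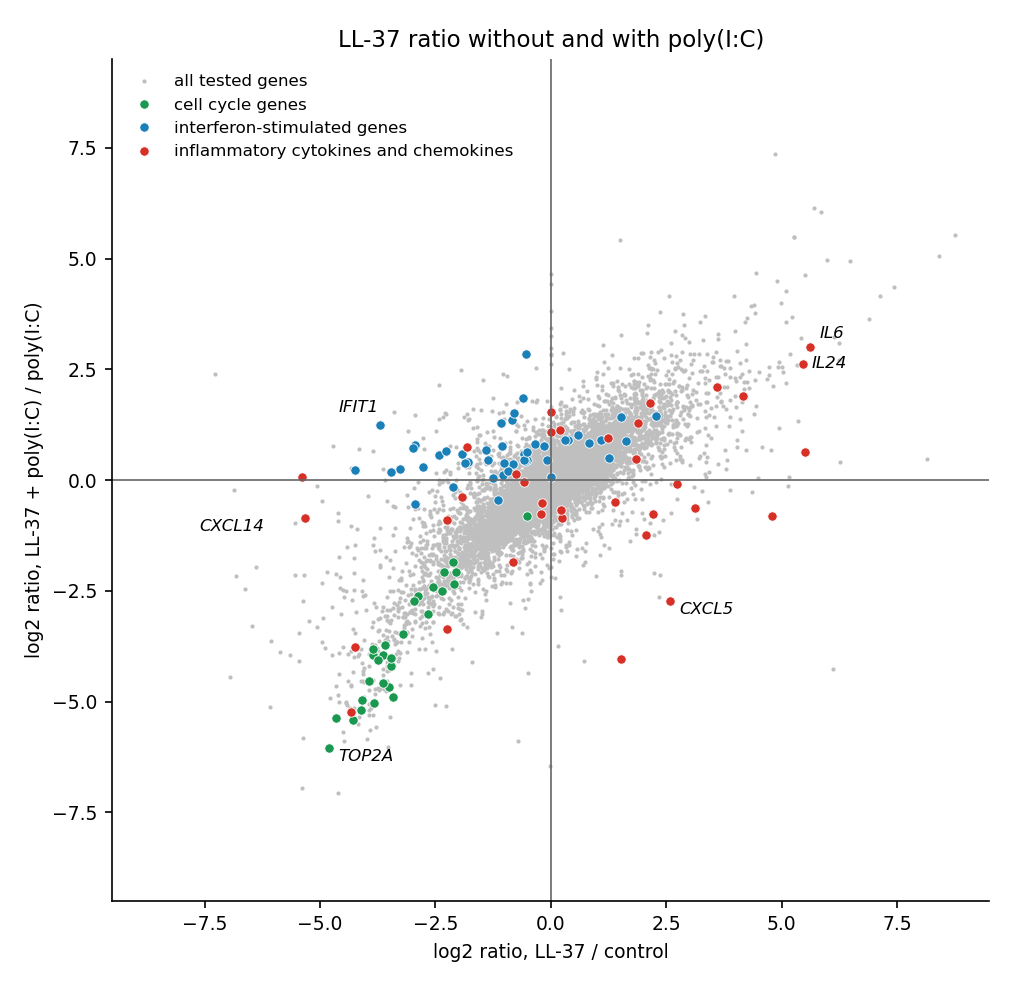
Log2 ratio of the LL-37 to the control library (horizontal axis) and of the co-treated to the poly(I:C) library (vertical axis) for each of 13460 genes (grey points), with 3 gene lists in colour; the pairs share no library. Cell cycle genes lay low on both axes (medians −3.48 and −3.94), while interferon-stimulated genes had medians of −0.89 and 0.59.

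To see whether the combination matched the single agents, the co-treated level was set against the product of the single-treatment ratios, with values above 0 meaning more than the product. Interferon-stimulated genes were above it: 30 of 46 were above, 0 below and 16 neither (median 1.34), with IFIT1 at 4.93 (4.46 to 5.41), OAS2 at 3.51 (3.24 to 3.78) and IFIT2 at 3.38 (2.96 to 3.80). Much of this came from lower levels with LL-37 alone, where 21 of 46 were lower than the control (median −0.885). Only 9 of 46 were higher in the co-treated than in the poly(I:C) library (median 0.589). IFIT1 was at −3.697 and 1.236 in those pairs. Several inflammatory, antimicrobial and differentiation genes that were higher with each agent were below it. The neutrophil chemokine genes CXCL3 at −5.58 (−6.07 to −5.09), CXCL5 at −5.32 (−5.64 to −4.99) and CXCL2 at −4.87 (−5.26 to −4.48) were far below it, and 16 of 35 inflammatory genes were below and 5 above (median −0.90). Antimicrobial genes had 6 of 11 below and 0 above (median −2.23), with S100A8 at −2.74, and differentiation genes 13 of 23 below and 0 above (median −1.75), with CRCT1 at −3.75 (−4.43 to −3.08). NF-κB genes had 8 of 20 below and 0 above (median −0.97), wound-activated genes 7 of 18 below and 1 above (median −0.53), and stress response genes 9 of 21 below and 0 above (median −0.76). Of growth factor genes 5 were above, 14 below and 31 neither, with EPGN at 3.33 (3.17 to 3.49), CTGF at 1.75 (1.64 to 1.86), INHBA at −2.88, FGF2 at −2.60 (−2.74 to −2.45) and HBEGF at −2.38 (−2.49 to −2.26). In all 503 genes were above and 702 below the product. That total of 1205 is no larger than the 1265 calls made among 13260 simulated unchanged genes when an assumed biological coefficient of variation of 0.2 was added to counting error, against 57 with counting error alone and 118 at an assumed value of 0.1. The spread between cultures was not measured, so the number of departures has no reference from these data. Against the sum of the single-agent excesses the counts were 1578 above and 373 below, but 807 of the 1578 had an expected sum at or under 1 read. By both references 368 genes were above and 262 below, and 34 were called in opposite directions. By that sum 8 interferon-stimulated genes were above and 0 below, 6 inflammatory genes above and 10 below, 3 antimicrobial genes above and 4 below, and 4 differentiation genes above and 7 below. NF-κB genes had 1 above and 2 below it, wound-activated genes 2 and 5, and stress response genes 2 and 2. Of 28 cell cycle genes 26 were called above the sum (median 7.337), but 0 were above and 6 below the product (median −0.325). Their medians were −3.483 with LL-37 and −0.653 with poly(I:C), at which the sum of excesses is negative. A sum under 1 read was set to 1 read, so the value of 7.337 cannot be read as a departure.

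**Figure D4:**
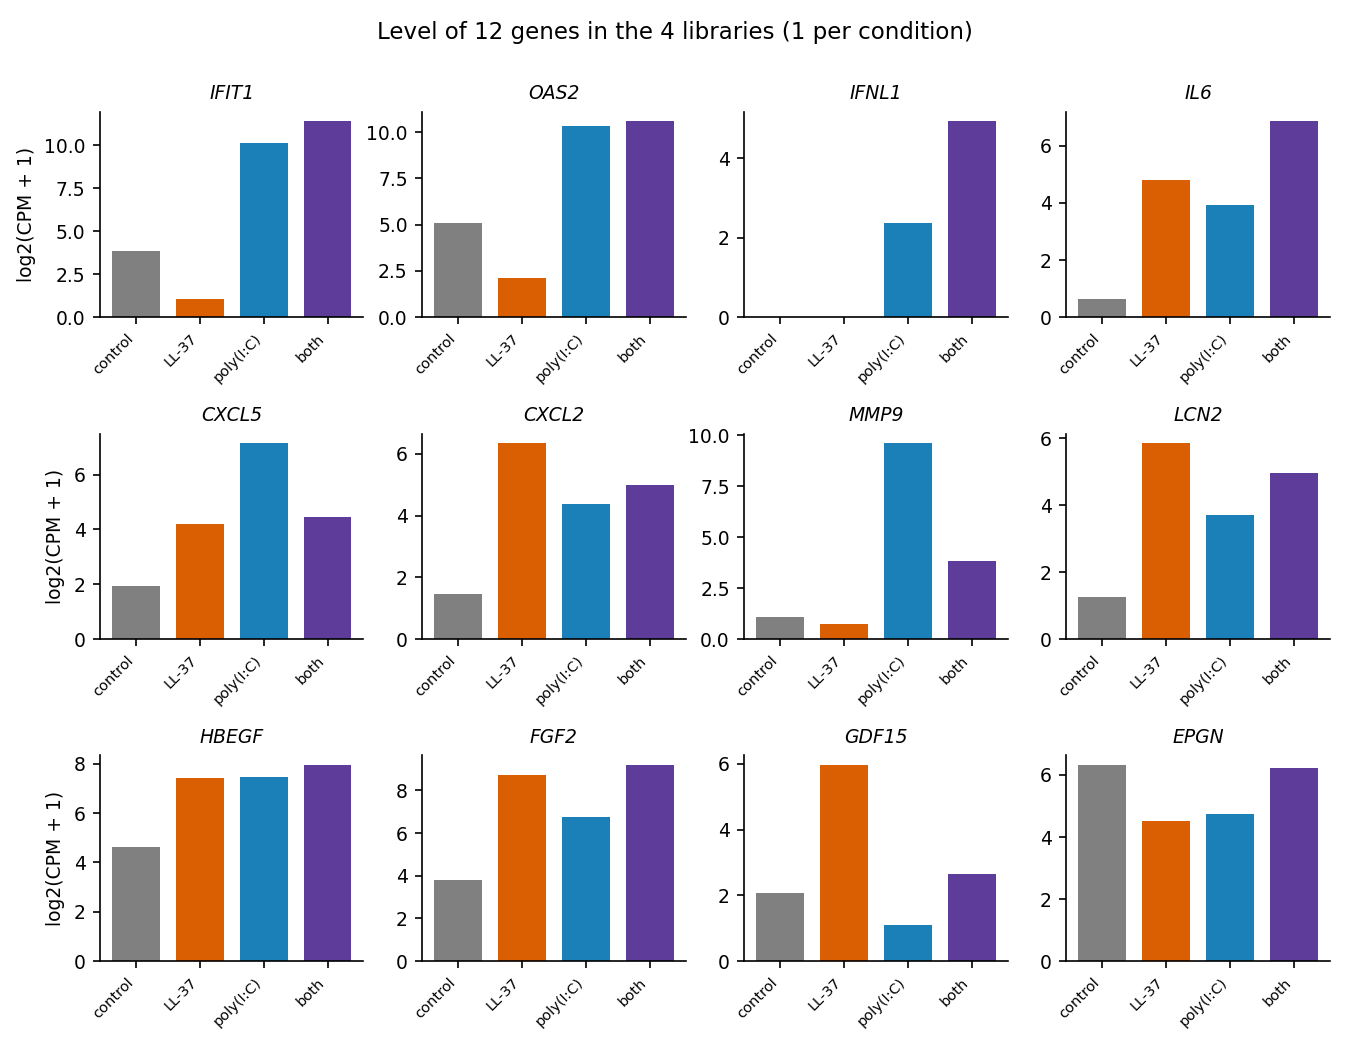
Level of single genes in the 4 libraries, as log2(CPM + 1) on an axis that starts at 0 and differs between panels; each bar is 1 library and has no error bar. IFIT1 was lower with LL-37 (−3.70) and CXCL5, MMP9 and CXCL2 were lower with both agents than with one of them (CXCL5 −2.73 and MMP9 −5.90 against poly(I:C), CXCL2 −1.37 against LL-37).

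The layout of 2 agents with and without each other allowed an additive model with both agents as terms and 1 residual degree of freedom, which takes departure from additivity as its spread. By edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, 435 of 13458 genes were higher and 70 lower with poly(I:C), and 2002 were higher and 2306 lower with LL-37. These counts depended on the settings: without an expression filter 40 were higher and 0 lower with poly(I:C), and 468 higher and 964 lower with LL-37. With DESeq2 size factors 606 were higher and 174 lower with poly(I:C), and a DESeq2 Wald test of the same model called 1099 higher and 540 lower. For poly(I:C) the calls included 40 of 46 interferon-stimulated genes, all higher (46 when adjusted over the list alone), and 17 of 18 MHC class I genes (18 adjusted over the list alone). MX2 was higher by 11.18 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00598) and IFIH1 by 5.54 (edgeR, adjusted p = 0.00923). For LL-37 they included 27 of 28 cell cycle genes, all lower (28 adjusted over the list alone), 15 of 20 cholesterol synthesis genes, all lower (16 adjusted over the list alone), and 11 of 20 p53 targets, all higher (11 adjusted over the list alone). TOP2A was at −5.39 (edgeR, adjusted p = 0.00853), HMGCS1 at −2.75 (edgeR, adjusted p = 0.00679) and MMP3 at 5.92 (edgeR, adjusted p = 0.00663). Several other lists had fewer calls in this model than in the single pairs. For poly(I:C) it called 12 of 35 inflammatory genes higher and 0 lower (23 and 2 adjusted over the list alone), 8 of 20 NF-κB genes higher (16 adjusted over the list alone), 4 of 18 wound-activated genes higher (11 and 1 lower adjusted over the list alone), 2 of 23 differentiation genes higher (5 and 1 lower adjusted over the list alone) and 0 of 11 antimicrobial genes (5 higher adjusted over the list alone). Of the cell cycle genes it called 2 lower with poly(I:C) (23 adjusted over the list alone). For LL-37 it called 3 of 20 NF-κB genes higher (2 adjusted over the list alone), 5 of 23 differentiation genes higher and 1 lower (5 and 1 adjusted over the list alone), 4 of 11 antimicrobial genes higher (4 adjusted over the list alone), and 5 inflammatory genes higher and 4 lower (5 and 4 adjusted over the list alone). Interferon-stimulated genes, of which 21 were lower with LL-37 alone, had 6 higher and 1 lower for the LL-37 term (5 and 1 adjusted over the list alone). Some lists had about as many calls for LL-37 as in the pair with the control: NRF2 targets had 9 higher and 2 lower (10 and 3 adjusted over the list alone), growth factor receptors 4 and 4 (6 and 5 adjusted over the list alone), stress response genes 8 and 4 (13 and 5 adjusted over the list alone) and double-stranded RNA sensing genes 5 and 1 (5 and 1 adjusted over the list alone). Of 6 interferon genes 4 were higher for the LL-37 term (4 adjusted over the list alone), against 0 with LL-37 alone. IFNB1, IFNL1, IFNL2 and IFNL3 had 0 reads in the control. For them the term rests mainly on the single pair of co-treated against poly(I:C). These p-values describe the 4 libraries of 1 cell source, and with only the tested agent in the model 0 genes were called for either term, against 810 and 4056 with an unadjusted p under 0.05.

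Of the 50 growth factor genes, 7 were higher and 3 lower for the poly(I:C) term of that model (11 and 6 adjusted over the list alone), and 8 were higher and 9 lower for the LL-37 term (8 and 9 adjusted over the list alone). For poly(I:C) they included VEGFC, MDK and CSF1, which were higher, and TGFB2 and KITLG, which were lower. KITLG was at −2.16 (edgeR, adjusted p = 0.0144) and VEGFC at 1.86 (edgeR, adjusted p = 0.0239). For LL-37 the higher genes included FGF2, FGF19 and GDF15, and the lower genes included PDGFC, ANGPTL4 and GAS6. FGF19 was at 5.72 (edgeR, adjusted p = 0.00781) and GAS6 at −1.63 (edgeR, adjusted p = 0.00995). HBEGF and INHBA, which were below the product of the single-agent ratios in the co-treated library, were not called for either term (edgeR, adjusted p = 0.206 and 0.137 for poly(I:C), 0.126 and 0.137 for LL-37).

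Markers of other cells were near absent. Of 8 endothelial markers 0 reached 1 CPM in any library, and the highest control level among them was 0.534 CPM. Of 10 fibroblast markers 1 reached it (COL1A1, 2.59 CPM in the control, 3.48 with LL-37, 7.25 with poly(I:C) and 6.87 with both), and of 8 melanocyte markers 1 (MITF, 7.40, 7.20, 2.96 and 2.67 CPM). Of 12 leukocyte and Langerhans cell markers 2 did: CD68, a lysosomal protein gene, was at 10.5, 14.4, 109.9 and 271.3 CPM, and CD74, the invariant chain gene, at 1.41, 0.548, 16.6 and 4.69 CPM. The leukocyte gene PTPRC stayed at or under 0.056 CPM. Of 23 ribosomal protein genes 0 were called with either single agent (medians 0.05 with LL-37 and −0.23 with poly(I:C)) and 1 was lower with both (median −0.32, RPL3 at −1.18, −1.20 to −1.15). The poly(I:C) median lay below the matched random range of −0.171 to 0.282. So did the median of −0.32 for co-treatment against LL-37, with a range of −0.212 to 0.192. Among 13 commonly used reference genes 1 was higher and 5 lower with LL-37 (median −0.47), 1 higher and 0 lower with poly(I:C) (median 0.06, and −0.13 with total counts only), and 2 higher and 4 lower with both (median −0.51). GAPDH was at −1.33 (−1.34 to −1.31) with LL-37 and B2M at 2.83 (2.81 to 2.85) with poly(I:C). The ribosomal RNA precursor took 0.768% of the counts in the control, 0.673% with LL-37, 2.887% with poly(I:C) and 0.592% with both.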

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

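Among the named genes, some had ratios for one agent that were called in opposite directions without and with the other agent. By definition the difference between the ratios of a gene is its departure from the product of the single-agent ratios. The opposite calls are therefore no separate result. That difference was not tested, and each ratio rests on 1 library per condition. The tests of library scaling, of the control library alone, of distortion by abundant genes and of the spread between RNAs without a poly(A) tail were chosen only after the result was seen. The LL-37 ratio was opposite for 11 named genes, given first without and then with poly(I:C): CXCL5 2.588 and −2.728, EPGN −1.825 and 1.503, EPHA4 −1.032 and 2.406, ICAM1 1.85 and −1.205, IFIT1 −3.697 and 1.236, IFNK −2.29 and 1.524, IGFBP6 −1.472 and 2.264, KRTAP2-3 −2.42 and 2.158, PLA2G4E 2.341 and −2.636, S100A8 1.062 and −1.679, and SPRR1A 1.712 and −1.379. The poly(I:C) ratio was opposite for 9 named genes, given first without and then with LL-37: CXCL2 3.5 and −1.369, EPGN −1.607 and 1.721, EPHA4 −1.862 and 1.576, FILIP1L 1.109 and −2.034, KRTAP2-3 −1.957 and 2.621, MXRA5 −2.164 and 2.769, RIMS2 −1.368 and 3.495, SLPI 2.919 and −1.191, and SPRR2D 1.609 and −1.023.

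Several of these genes belong to lists whose co-treated level departed from the product of the single-agent ratios, with interferon-stimulated genes above and inflammatory, antimicrobial and differentiation genes below. Since the opposite calls are made of the same values, they lend that pattern no further support. Low counts were argued against, since members with at least 20 reads in every library had medians of 1.141 (36 of 46 interferon-stimulated genes), −1.881 (17 of 35 inflammatory), −2.484 (4 of 11 antimicrobial) and −1.793 (18 of 23 differentiation). A deviation of the single control library cannot be told apart from the pattern: against poly(I:C), without the control, the list medians of the co-treated library were at percentiles 100 (interferon-stimulated), 2.56 (inflammatory), 95.64 (antimicrobial) and 25.59 (differentiation). A general trait of genes higher with each agent cannot be told apart either, since 471 such genes outside the lists had a median of −1.094, against −2.416 for 37 list members and −0.1765 or −0.4505 in simulated data following the product at an assumed biological coefficient of variation of 0.1 or 0.2. The 5 interferon-stimulated genes higher with each agent had a median of −0.754, below the product, unlike their list. Against the sum of excesses the medians were 0.60, −0.38, −0.38 and −0.42, and 8 interferon-stimulated genes were above instead of 30, so both the size and the number of calls depended on the reference.

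Cell cycle genes were lower with LL-37 whether or not poly(I:C) was present. Transcript length and GC content were argued against, since the median nearest 0 was −3.424 after their trend was removed for 12718 genes (94.49% of those tested). The choice among scalings did not produce this, the median nearest 0 over 3 scalings being −3.439. Scaling as such was not decided, since the factors were too alike to move the median far. For control and LL-37 they were 1.0519 and 1.0849 by TMM, 1.0447 and 1.0866 by DESeq2 size factors, and 1.0236 and 1.0755 by upper quartile. A lower share of dividing cells and a difference in cell density between the wells were not tested, and both stay open.

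The ribosomal RNA precursor RNA45S5 was at 7297 CPM in the control, 6207 with LL-37, 31179 with poly(I:C) and 6252 with both. RNAs of classes taken to lack a poly(A) tail did not all rise as much as this precursor. They were picked by gene symbol, 41 in all, and the absence of a tail was not checked. Their median log2 ratio of poly(I:C) to LL-37 was −0.01848 (bootstrap 95% range −0.3226 to 0.2976), against 2.329 for RNA45S5. The standard deviation between members was 1.719 for poly(I:C) to LL-37. This pair was picked because its median lay nearest 0. The median of the 41 RNAs was 0.4851 against the control and −0.5048 against co-treatment, and the classes went both ways against the control (1.339 for 24 histone genes, −0.2244 for 15 small nuclear and nucleolar RNAs). The 24 histone genes were at −0.3734 against LL-37 and −0.9785 against co-treatment. Their sign thus changed with the library compared, so the pooled median cannot decide on carry-over. The 15 small nuclear and nucleolar RNAs were at 0.1156 against LL-37 and 0.09235 against co-treatment. Looked at after their values were seen, RMRP (0.394, 0.657, 9.24 and 0.528 CPM) and RPPH1 (0.478, 0.548, 5.10 and 0.808 CPM) were higher in the poly(I:C) library, with a median of 3.942 against the control, so carry-over of some RNAs stays open. Leaving out the 10 most abundant genes moved no count of genes higher or lower with poly(I:C) by more than a ratio of 1.005. TMM trims genes with extreme ratios or levels in either case, so this could hardly have shown a distortion. It shows only that the counts under TMM did not rest on those genes. No biological explanation was tested.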

How the results depend on the processing

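None of the tests in this part was chosen after the result was seen. Of 2568 values of named genes under alternatives, 2552 kept direction and call, 16 lost the call and 0 reversed. These covered 642 ratios that had been called, many of them picked for extreme intervals, so that stability was likely from the start. The alternatives for them were only DESeq2 size factors, total counts, upper-quartile factors and a prior count of 5. Of 468 list medians 454 stayed within the bootstrap 95% range over members, 12 moved out of it and 2 reversed, where reversed means that the list lay outside the middle 95% of random lists and changed sign. Among the others 31 changed sign from a median inside that range. Of 312 list percentiles 291 stayed and 21 moved, and of 130 counts of genes 101 stayed within 1.5 times and 29 moved. With total counts only, lower genes numbered 845 for poly(I:C) against control (543 by TMM) and 983 for co-treatment against LL-37 (603). The 5 CPM filter tested fewer genes and left 298 lower with poly(I:C) and 314 above the product. The 4-fold rule, stricter by construction, gave 527 higher and 689 lower with LL-37, 511 and 111 with poly(I:C), 939 and 848 with both, 240 and 525 for co-treatment against poly(I:C), 436 and 68 against LL-37, and 150 above and 161 below the product. Against the sum of excesses 1578 were above and 373 below, and 807 of the 1578 had a sum at or under 1 read. The Spearman correlation for the poly(I:C) pair was 0.602. In the additive model, poly(I:C) had 174 lower with DESeq2 size factors, 40 higher and 0 lower without a filter, 1099 and 540 by the DESeq2 Wald test, and 0 and 0 with the tested agent only (810 at an unadjusted p under 0.05). LL-37 had 468 and 964 without a filter and 0 and 0 with the tested agent only (4056 unadjusted). With the other agent left out, its effect enters the residual spread by construction. The median of EGF family ligands for co-treatment against LL-37 was −0.206 with the 5 CPM filter (0.512 otherwise), and the mean of other growth factors for co-treatment against control was 0.34 (median −0.853). Depth limits genes with few reads, such as EGF with 18 in the control and 3 with LL-37. For the remaining shifts the cause was not tested. No paired analysis was possible because each group has 1 library and replicate numbers pair nothing, while the additive model compares each agent within the levels of the other.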

Other observations

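No test was run for this part. Genes outside the lists added to the picture with LL-37. The transglutaminase gene TGM2 was at −5.25 (−5.47 to −5.04), the interleukin-7 receptor gene IL7R at −4.96 (−5.35 to −4.62) and the gap junction gene GJA5 at −6.05 (−7.36 to −5.16) in LL-37 against control. Each is a comparison of 1 library with 1 library.

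The ligand gene KITLG and the melanocyte marker MITF were both lower in the 2 libraries with poly(I:C), KITLG at −2.08 with poly(I:C) and −1.64 with both, and MITF at 2.96 and 2.67 CPM against 7.40 in the control. The other melanocyte markers do not tie this to melanocytes. TYR, DCT and SOX10 were at 0 CPM in every library and KIT at most at 0.056. PMEL was at 0.731, 0.466, 0.56 and 0.839 CPM in the control, LL-37, poly(I:C) and co-treated libraries. TYRP1 was at 0.169, 0.493, 0.28 and 0.621 CPM, and MLANA at 0.253, 0.11, 0.249 and 0.177 CPM. No explanation was tested.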
